A study of Streptomyces clavuligerus with 15 samples.

How the data were processed

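The series holds RNA-seq libraries of 5 strains of Streptomyces clavuligerus, 3 libraries per strain. Per the labels, the cultures were grown in triplicate in tryptone soy broth, the RNA was treated with DNase, and messenger RNA was taken with poly-T beads before random-primed synthesis of cDNA. The authors' files hold, for each library, estimated counts and TPM for each annotated gene, per the file headers. Reads were assigned with Salmon and compared with DESeq2 by the authors, per the submitters' processing notes, which give no version. The setting for the strand of the reads is not stated. Counts from genes that overlap on opposite strands are therefore treated as uncertain. The deposited estimated counts are not normalized, and between 0.573% and 0.999% of genes in a library have a count that is not whole. The deposited TPM divide by effective length and have the same sum in each library. Coordinates, products and gene symbols are those of the deposited SC2 annotation, whose scores were not used. It lists 6839 features on 5 sequences, 862 of them with a gene symbol. The 33 features without counts are identical in sequence to a counted one.

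Strain and replicate were taken from the labels, and no library was left out of the primary analysis. Counts were rounded, filtered with edgeR's filterByExpr (5917 genes kept, 889 left out) and scaled with TMM. A quasi-likelihood model with 1 mean per strain was fitted to all 15 libraries with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Each strain was compared with SC2 and each strain number with the one before, 7 comparisons in all. A further test with the same model asked which genes differ among the 5 strains. P-values are 2-sided and adjusted by Benjamini and Hochberg within a comparison, with a threshold of 0.05. The common biological coefficient of variation was 0.242. CPM in the text are scaled by TMM. Depth per library is given at the start of the results. A strain with 0 reads of a gene was set to a floor of 3 reads over its libraries, which gives the lowest fold change the counts allow.

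A set of 29 gene lists was drawn up from product names and symbols before the data were examined, as were the comparisons, the tests, the rule for naming genes and the alternatives not marked otherwise. Lists with at least 5 tested members, 27 of them, were tested with camera at an inter-gene correlation of 0.0100 on log2 CPM with a prior count of 2. In 5 lists 19 members had been matched by text to another function. The interval around the main biosynthetic genes was set by the longest set of product-matched members within 100 kb, and its camera p-values were adjusted over its 7 comparisons. The share of reads from each sequence, without structural RNA, was compared among strains with an exact permutation test of F over all 1401400 splits into groups of 3, on log-odds. A gene counted as silent with under 3 reads in each library of a strain and at least 10 in each library of the other. A run is 3 or more such neighbours. The share of SC2 in a library was fitted by non-negative least squares over coding genes longer than 600 bp with more than 500 reads in all. Near-identical copies were sought with blastn 2.17.0 (at least 95% identity over 100 bp). They affect 120 genes, and 114 genes overlap another by more than 50 bp, 100 of them on the opposite strand. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

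Genes named against SC2 are the 6 largest rises and 6 largest falls among genes past the threshold with a change of at least 1 log2 unit, libraries that do not overlap, a mean of at least 10 CPM and a product that is not hypothetical. For successive strain numbers the limit was 3 in each direction. Up to 4 members of a list with the smallest p-values, a fixed choice of antibiotic and signalling genes, and the genes at the ends of silent runs were named too. List members that moved against their list, the 14 genes shared by all comparisons with SC2 and the silent left end of sequence 5 were picked after their values were seen.

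Whether equal replicate numbers pair libraries was checked with the correlation of their residuals, with all 3 pairs above 0.1 as the rule. This held for SC3 against SC2 (lowest r 0.169), SC4 against SC3 (0.239), SC5 against SC4 (0.133) and SC6 against SC5 (0.151). It did not for SC4 (0.0545), SC5 (-0.0759) and SC6 (-0.000177) against SC2. In SC4 against SC3, SC5 against SC4 and SC6 against SC5 the highest r was that of the shallow replicate 2 (0.472, 0.349 and 0.295). The check therefore cannot part culture blocks from a feature that the shallow libraries share. The labels do not say that the replicates were grown as blocks, so the replicate number as a block is an alternative. With it, 190, 1347, 3462 and 401 genes changed in SC3 to SC6 against SC2, 459, 3034 and 3130 between successive strains, and 3786 among the 5 strains. Other alternatives were DESeq2 1.42.0, limma-voom, other size factors, filters of no minimum and of 50 reads in 3 libraries, structural RNA left out, effective lengths as offsets, only the libraries of the strains compared, fry, camera with an estimated correlation, other limits for silent runs, and each library left out in turn. Leaving out the 4 shallow libraries, taking mismatched members out of lists, and DESeq2 size factors for the lists were added after the data were seen.

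The count tests were tested on simulated data with 200 changed genes per comparison and fits of 5806 to 5837 genes. Over the 7 comparisons, 30.0% to 56.2% of 2-fold changes, 85.7% to 90.0% of 4-fold and 86.0% to 95.9% of 8-fold changes were recovered, and at most 12.2% of 1.5-fold ones. False calls made up 3.33% to 8.06% of calls. The test among 5 strains recovered 178 of 200 genes changed 4-fold, with 7 false calls over 5849 genes. Camera called the shifted list in each of the 7 comparisons. The search for silent runs found 3 of 3 planted runs. The mixture fit returned 0.0971, 0.200 and 0.399 for planted SC2 shares of 10%, 20% and 40%. The planted mixtures were made from the same libraries as the sources, with counting noise alone. Recovery was therefore near certain, and error between replicates was not measured.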

Results

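The series measured messenger RNA in 5 strains of Streptomyces clavuligerus, SC2 to SC6, a filamentous bacterium that makes the beta-lactamase inhibitor clavulanic acid and the antibiotic cephamycin C. Each strain has 3 replicate libraries from liquid cultures, 15 in all. The series title speaks of a domesticated lineage, and the labels do not say whether the strain numbers give its order. Sample titles put the harvest in the middle of logarithmic growth, and the growth protocol puts it late in exponential growth. Reads were assigned to 6806 genes of the SC2 annotation: 6723 coding genes, 73 tRNA genes, 9 rRNA genes and 1 gene for transfer-messenger RNA. These genes lie on the chromosome (sequence 1, 6748915 bp) and on sequences 2, 3, 4 and 5 of 11722, 148877, 448847 and 835972 bp. Of them, 5917 had enough reads to be tested. Fold changes are log2 values of the first strain over the second, counts scaled to library size (CPM) are means ± SD over the 3 libraries of a strain, and adjusted p-values come from edgeR's quasi-likelihood test unless another test is named. They measure the spread between these libraries, which the labels call triplicates. Positions are those of the deposited SC2 annotation. Floors cover counting error only. For a gene list, the range after the word alternatives is that of its adjusted p over the other ways to run camera. Its highest value came each time from camera with the correlation between genes estimated from the data, a setting in which the lists did not pass. Where a called log2 change moved by more than 1.5-fold without 1 library, or without the 4 shallow ones alone, its value is given at the end of the paragraph, or a lower bound where the strain's other libraries held 0 reads.

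Depth fell into separate ranges. The 3 SC2 libraries and replicates 1 and 3 of the other strains held 6675054 to 8749442 assigned reads, and replicate 2 of SC3, SC4, SC5 and SC6 held 1779749 to 1930271. Between 6225 and 6528 genes had a read in a library. The transfer-messenger RNA, which frees stalled ribosomes, took 9.28% to 22.2% of the reads of a library, with strain means of 18.8% ± 0.724 in SC2 and 14.3% ± 2.70 in SC4 (SD, n = 3). In the 4 shallow libraries its share was 17.2% to 22.2%. Ribosomal RNA took 1.13% to 3.96%. Its strain mean was 3.46% ± 0.432 in SC5 and 1.88% to 1.97% in the others, and all 3 SC5 libraries lay above the 12 others.

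Across all 5 strains, 3286 of 5917 genes differed in level. The genes of sequence 5, the largest extrachromosomal element and the home of many specialised-metabolism genes, took smaller shares in SC4 and SC5 than in SC2. They took 12.9% ± 1.53 of gene reads in SC2 (SD, n = 3), 11.4% ± 1.10 in SC3, 8.05% ± 1.19 in SC4, 3.65% ± 2.02 in SC5 and 11.3% ± 0.920 in SC6 (exact permutation test over all 1401400 splits of the libraries, adjusted p = 0.000178). The highest SC5 share, 5.94%, was that of the shallow replicate 2, whose profile lies between those of SC5 and SC2. Without replicate 2 the mean was 2.51% in SC5, 7.44% in SC4 and 12.6% in SC2. Chromosomal genes moved the other way, from 81.9% ± 1.14 in SC2 to 92.4% ± 2.41 in SC5 (exact permutation test, adjusted p = 0.000178). The shares of a library add up to a fixed total, so this largely mirrors sequence 5 and is not a separate result. The small sequence 2 gave 0.212% ± 0.0148 of gene reads in SC2 and less in each other strain, from 0.0578% ± 0.0273 in SC5 to 0.102% ± 0.0189 in SC4 (exact permutation test, adjusted p = 0.00346). Without replicate 2 its mean was 0.0427% in SC5 and 0.213% in SC2. In SC2, 89.8% ± 0.728 of the sequence 2 reads were of SCLAV_SC2_27935, whose level is uncertain as a near-identical copy lies on sequence 5. Without genes that have such a copy, sequence 2 took 0.0137% in SC2 and 0.00574% to 0.00690% in the others (exact permutation test, adjusted p = 0.0168). Sequence 4 took 2.90% ± 0.259 in SC5 and 3.91% ± 0.353 in SC2 (exact permutation test, adjusted p = 0.00771), while by TPM SC3 and SC6 were lower than SC5 (3.75% and 3.61% against 3.85%). For sequence 3 the exact permutation test gave an adjusted p of 0.253, 0.124 with structural RNA kept in the total and 0.0251 with shares of TPM.

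**Figure D1:**
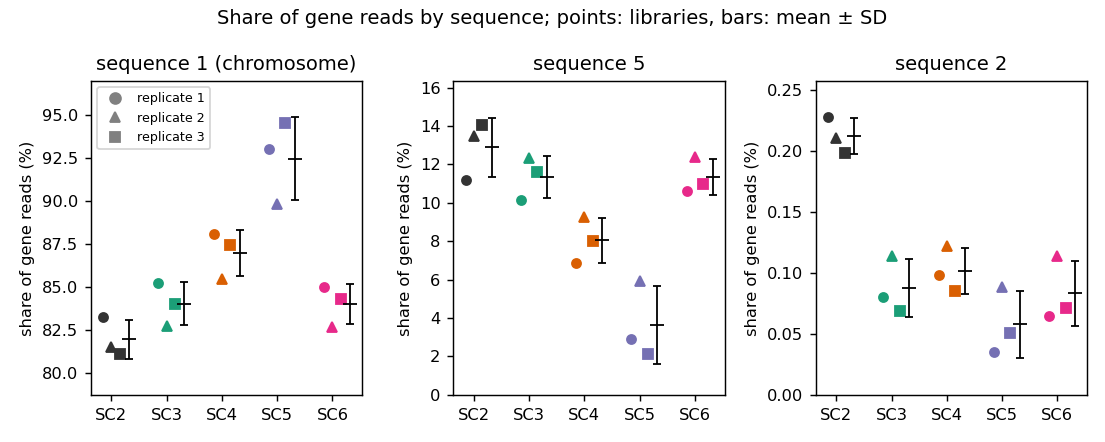
Share of gene reads (%) from sequences 1, 5 and 2 in each strain; points are libraries and bars are the mean ± SD. The sequence 5 share was 3.65% ± 2.02 in SC5 and 12.9% ± 1.53 in SC2. Without replicate 2 the means were 2.51% and 12.6%.

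The comparisons with SC2, the strain whose annotation the files use, ask which transcripts each other strain holds at another level. SC3 had the fewest calls. A putative transmembrane efflux protein, SCLAV_SC2_03140 (chromosome, 841306–842583), of a class that pumps compounds out of the cell, rose from 145 ± 17.5 to 639 ± 179 CPM (SD, n = 3), 2.14 ± 0.31 log2 (SE, adjusted p = 0.00151). A pair of neighbouring genes of sequence 5 rose with it: malate synthase aceB, an enzyme of the glyoxylate shunt, by 1.73 and the dehydrogenase SCLAV_SC2_31755 of the kind used in fatty-acid breakdown by 1.89. The kinase inhibitor gene kipI rose by 1.66, the acetyltransferase SCLAV_SC2_00730 by 1.56 and the secreted protein SCLAV_SC2_00610 by 1.47. Several of these rises are not particular to SC3. For aceB, SCLAV_SC2_31755 and kipI the libraries of SC4 and SC6 also all lay above those of SC2. For SCLAV_SC2_00610 those of SC5 and SC6 did. In SC4 aceB had 146, 86.8 and 107 CPM, against 76.6, 47.0 and 86.2 in SC3. On sequence 4 the DNA-binding protein SCLAV_SC2_29430 fell from 46.9 ± 11.7 to 11.03 ± 4.65 CPM (-2.20), and the neighbouring regulator SCLAV_SC2_29425 changed by -2.08. The chromosomal DNA primase/polymerase SCLAV_SC2_22085, a class found on mobile elements, changed by -2.15 ± 0.29 (SE, adjusted p = 0.00104). The protease SCLAV_SC2_17030 (trypsin-like), the enediyne gene unbV1 and the regulator SCLAV_SC2_11755 fell as well (-1.87, -1.64 and -1.63). Of 27 tested gene lists 1 passed (3 without SC2 replicate 1), that of ribosomal proteins, whose median was 0.36 over 53 genes (camera adjusted p = 1.37e-06, alternatives 3.61e-08 to 0.997). Single ribosomal protein genes numbered 0 past the threshold in edgeR, 5 at an unadjusted p under 0.05, 0 adjusted over the list alone, and 0 in DESeq2 and 0 in limma-voom. Of the 21 genes of the beta-lactam supercluster described below, edgeR called 0, 0 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 (median -0.06, camera adjusted p = 0.561, alternatives 0.356 to 0.954, and 0.0367 without SC2 replicate 1). Without SC3 replicate 2 the changes were -2.55 for SCLAV_SC2_17030 and -2.70 for SCLAV_SC2_29425.

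In SC3, 93 genes changed, 57 higher and 36 lower, 73 of them by at least 1 log2 unit. With the replicate number as a block the count was 190, and without the 4 shallow libraries it was 213; limma-voom gave 146 and DESeq2 143, and scaling on chromosomal genes split the calls into 43 higher and 42 lower. The count was 33 without SC2 replicate 2, 19 without SC2 replicate 3, 14 without SC3 replicate 1 and 20 without SC3 replicate 3. Leaving out 1 library ended these calls (adjusted p in brackets): SCLAV_SC2_31755 without SC2 replicate 3 (0.05003), SCLAV_SC2_00610 without SC2 replicate 2 (0.0725), SC2 replicate 3 (0.0734), SC3 replicate 1 (0.0877) or SC3 replicate 3 (0.0626), SCLAV_SC2_29425 without SC2 replicate 1 (0.0735), SC2 replicate 2 (0.103), SC2 replicate 3 (0.103), SC3 replicate 1 (0.167) or SC3 replicate 3 (0.175), SCLAV_SC2_17030 without SC2 replicate 2 (0.139), SC2 replicate 3 (0.152), SC3 replicate 1 (0.146) or SC3 replicate 3 (0.183), unbV1 without SC2 replicate 1 (0.0661), SC2 replicate 2 (0.0996), SC2 replicate 3 (0.139), SC3 replicate 1 (0.240) or SC3 replicate 3 (0.259), SCLAV_SC2_11755 without SC3 replicate 1 (0.0736) or SC3 replicate 3 (0.0747).

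Most tested genes of the list for arginine and ornithine metabolism rose in SC4. Not all its members make arginine: it also holds the arginine repressor, an arginase and oat2 of the beta-lactam supercluster. Arginine is a precursor of clavulanic acid, and 9 of 14 tested genes rose (11 higher and 0 lower adjusted over the list alone), with a median of 1.24 (camera adjusted p = 4.54e-06, alternatives 3.21e-06 to 0.682). Ornithine carbamoyltransferase SCLAV_SC2_23535 went from 61.0 ± 4.09 to 178 ± 31.1 CPM (SD, n = 3), 1.55 ± 0.25 log2 (SE, adjusted p = 0.00110). Argininosuccinate lyase arlY rose by 1.71, acetylglutamate kinase argB by 1.45 and the arginine repressor SCLAV_SC2_03885 by 1.14, all in one stretch of the chromosome. Ribosomal protein genes rose too: 36 of 53 tested genes rose and 1, SCLAV_SC2_10150, fell (43 higher and 1 lower adjusted over the list alone), median 0.94 (camera adjusted p = 2.86e-20, alternatives 1.38e-21 to 0.682), led by rpsH (1.19) and rplF (1.08). For glycolysis, which makes the other clavulanic acid precursor, 7 of 24 tested genes rose (10 higher and 1 lower adjusted over the list alone), median 0.37 (camera adjusted p = 0.000846, alternatives 0.000597 to 0.794), among them glyceraldehyde-3-phosphate dehydrogenase SCLAV_SC2_26880, from 2054 ± 205 to 4706 ± 859.6 CPM (1.196), phosphoglycerate mutase gpmA1 (1.61) and the dikinase SCLAV_SC2_08120 (1.28). For the tricarboxylic acid cycle, 7 of 20 tested genes rose and 1, SCLAV_SC2_19220, fell (7 higher and 1 lower adjusted over the list alone), median 0.45 (camera adjusted p = 0.0247, alternatives 0.0108 to 0.794), with the succinate dehydrogenase membrane subunit SCLAV_SC2_18375 at 1.03. For the enzymes that charge tRNAs, 7 of 27 tested genes rose and 1, SCLAV_SC2_32280, fell (12 higher and 1 lower adjusted over the list alone), median 0.49 (camera adjusted p = 0.000501, alternatives 2.28e-05 to 0.794); the prolyl-tRNA editing homologue SCLAV_SC2_32280 fell by 0.75. Leaving out 1 library ended these calls (adjusted p in brackets): tricarboxylic acid cycle without SC2 replicate 2 (0.0557) or SC4 replicate 3 (0.0751), SCLAV_SC2_18375 without SC2 replicate 2 (0.0635) or SC2 replicate 3 (0.0644), SCLAV_SC2_10150 without SC2 replicate 2 (0.146), SC2 replicate 3 (0.136), SC4 replicate 1 (0.185), SC4 replicate 2 (0.0524) or SC4 replicate 3 (0.0932), SCLAV_SC2_19220 without SC2 replicate 2 (0.0891), SC2 replicate 3 (0.0755) or SC4 replicate 1 (0.102).

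Single genes with the largest rises in SC4 lay in a few places. The integral membrane protein SCLAV_SC2_15285 and the neighbouring MarR-family regulator SCLAV_SC2_15290, of a family that often controls drug efflux, rose from 50.9 ± 11.2 to 372 ± 63.4 CPM (2.87 ± 0.25 log2, SE, adjusted p = 5.56e-06) and by 2.58. The radical SAM protein SCLAV_SC2_24740 rose by 3.43 and the nonribosomal peptide synthetase SCLAV_SC2_25785, an assembly-line enzyme, by 2.88. Near the left end of sequence 5, the MauE-domain protein SCLAV_SC2_30915 and the bacteriocin exporter homologue SCLAV_SC2_30905 rose by 3.35 and 2.78, while the esterase SCLAV_SC2_30870 at its first bases fell (-2.93; adjusted p = 0.0252). On sequence 4 the ATPase-domain protein SCLAV_SC2_29335 fell from 15.7 ± 1.02 to 2.31 ± 0.895 CPM (-2.94), with the secretion-signal protein SCLAV_SC2_29415 (-2.14) and the regulator SCLAV_SC2_29425 (-2.12). The primase/polymerase SCLAV_SC2_22085 (-2.64) and the MutT-family protein SCLAV_SC2_33720 (-2.13) fell as well. In the clavam cluster, whose products resemble clavulanic acid, cvm1 went from 185 ± 22.4 to 752 ± 216 CPM (2.02 ± 0.41) and cvm3 rose by 2.02; in the supercluster, median -0.34 (camera adjusted p = 0.0560, alternatives 0.0508 to 0.876), oat2 alone passed in edgeR (1.30), and the list test gave 0.00365 without SC2 replicate 1 and 0.0157 without SC4 replicate 3. In all, 836 genes changed, 496 higher and 340 lower, 305 by at least 1 log2 unit. The count was 1339 without the 4 shallow libraries, 1347 with a replicate block, and 256 without SC2 replicate 2, 240 without SC2 replicate 3, 182 without SC4 replicate 1 and 325 without SC4 replicate 3. The split was 401 higher and 485 lower with scaling on chromosomal genes, 427 and 421 with structural RNA left out, and 522 and 243 with library size. Leaving out 1 library ended these calls (adjusted p in brackets): SCLAV_SC2_30870 without SC2 replicate 2 (0.0843), SC2 replicate 3 (0.0897), SC4 replicate 1 (0.146) or SC4 replicate 3 (0.105), SCLAV_SC2_29415 without SC2 replicate 2 (0.0510), SC2 replicate 3 (0.0520), SC4 replicate 1 (0.0971) or SC4 replicate 3 (0.0724), SCLAV_SC2_33720 without SC2 replicate 2 (0.0762), SC2 replicate 3 (0.0841), SC4 replicate 1 (0.144) or SC4 replicate 3 (0.115), SCLAV_SC2_29425 without SC4 replicate 1 (0.0561), cvm3 without SC2 replicate 2 (0.123), SC2 replicate 3 (0.113), SC4 replicate 1 (0.102) or SC4 replicate 3 (0.0851). Leaving SC4 replicate 2 out gave -2.81 for SCLAV_SC2_29415, -2.79 for SCLAV_SC2_29425 and -2.85 for SCLAV_SC2_33720.

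SC5 held lower levels of most beta-lactam genes. In the supercluster that joins the clavulanic acid and cephamycin C genes (chromosome, 4841775–4880987), 20 of 21 genes fell (21 adjusted over the list alone), with a median of -1.78 (camera adjusted p = 1.87e-08, alternatives 4.44e-09 to 0.438). Without the 4 shallow libraries its median was -2.16. The pathway activator ccaR went from 3073 ± 655 to 781 ± 401 CPM (SD, n = 3), -1.98 ± 0.30 log2 (SE, adjusted p = 3.59e-05). Lysine aminotransferase lat, the first enzyme of the cephamycin branch, fell to 699 ± 387 CPM (-1.92), the peptide synthetase pcbAB by 2.08 and isopenicillin N synthase pcbC by 2.54. Carboxyethylarginine synthase ceaS2, the first enzyme of clavulanic acid, went from 11561 ± 2301 to 3230.5 ± 1146 CPM (-1.84), and pah2 (-1.78), cas2 (-2.05), the regulator claR (-1.24) and oat2 (-0.78) were lower. Of the clavam genes, cvm1 fell to 23.1 ± 17.1 CPM (-3.09), cvm3 by 3.33 and their regulator cvm7 by 2.07, while edgeR did not call cvm11 (0.87) and cvm12 (-0.25). Of 4 copies of pathway genes on sequence 5, edgeR called 3 higher, mainly in replicate 1: pah1 by 3.80 (adjusted p = 0.00227), ceaS1 by 3.26 (adjusted p = 0.0166), with 33.8, 13.1 and 1.05 CPM in SC5 replicates 1 to 3, and bls1 by 3.27 (adjusted p = 0.00860), with 41.5, 11.2 and 1.37. Replicate 3 of SC5 lies within the range of SC2 for ceaS1 and bls1. The fourth, oat1, was not called (0.31), with 4.91, 1.46 and 0.530 CPM in SC5. Of 4 butyrolactone genes, whose products make or bind a signal molecule, 2 had enough reads to be tested and fell: SCLAV_SC2_31200 by 3.83 and the receptor gene brp by 1.16. By list, 19 of 26 tested genes fell and 3, ceaS1, bls1 and pah1, rose (4 higher and 19 lower adjusted over the list alone) for clavulanic acid and clavams, median -1.74 (camera adjusted p = 8.97e-05, alternatives 1.54e-05 to 0.598), and 14 of 14 tested genes fell (0 higher and 14 lower adjusted over the list alone) for cephamycin C, median -1.86 (camera adjusted p = 1.66e-05, alternatives 3.03e-06 to 0.598). Scaling by library size ended the call of oat2 (-0.47), and leaving out 1 library ended others (adjusted p in brackets): ceaS1 without SC2 replicate 1 (0.0606), SC2 replicate 2 (0.0566) or SC5 replicate 1 (0.170), bls1 without SC5 replicate 1 (0.133). The fit without SC5 replicate 2 gave -3.73 for cvm1, -4.47 for cvm3, -3.41 for pcbC and -5.47 for SCLAV_SC2_31200. Without SC5 replicate 3 the changes were -3.21 for SCLAV_SC2_31200. Leaving SC5 replicate 1 out gave 1.75 for ceaS1, 1.40 for bls1 and 2.10 for pah1.

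**Figure D2:**
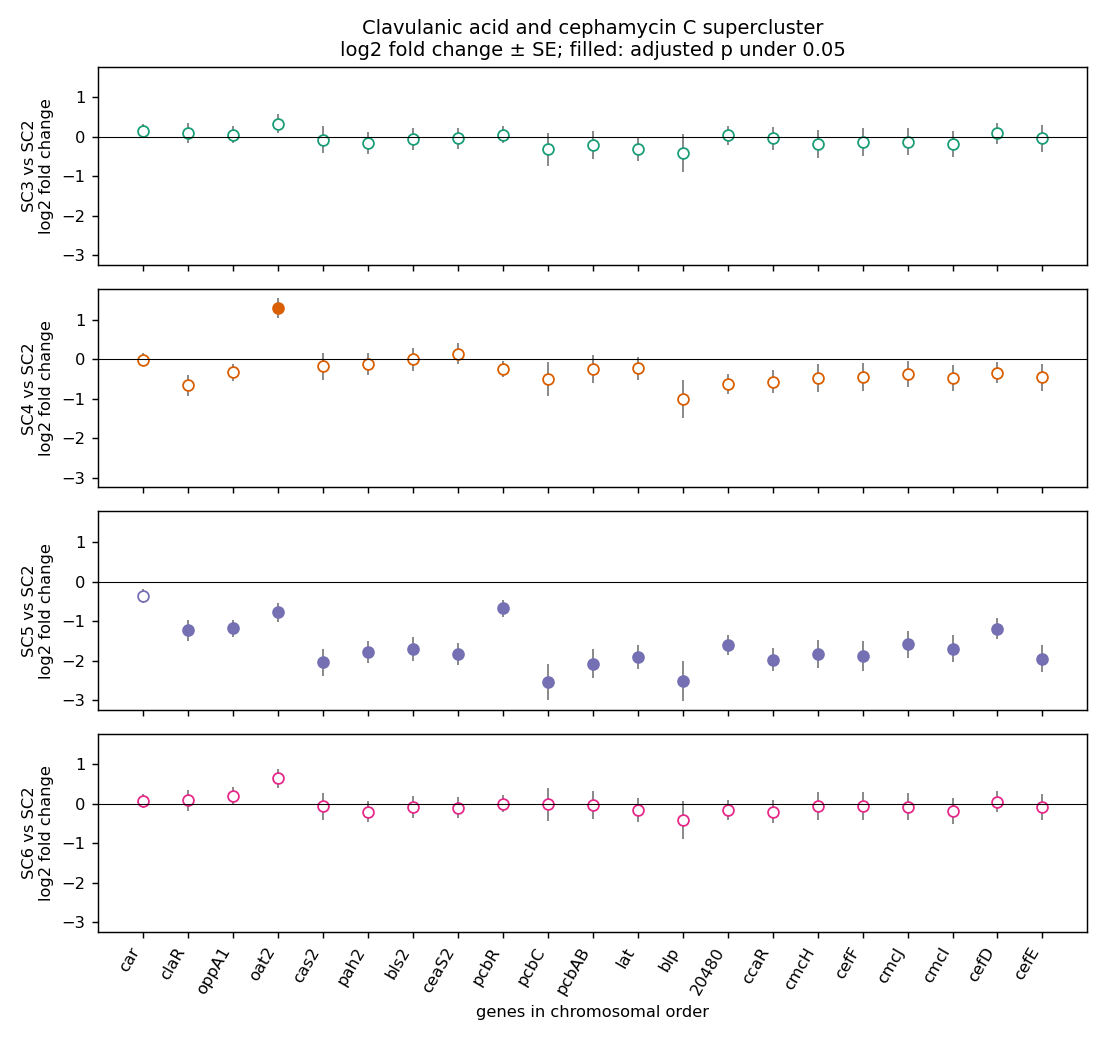
Log2 fold change against SC2 ± SE of the 21 genes of the beta-lactam supercluster in chromosomal order, for SC3, SC4, SC5 and SC6; filled points have an adjusted p under 0.05. In SC5 20 genes are filled, all below 0.

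The largest rise in SC5 was that of an amidotransferase annotated as acting on glutamine and fructose 6-phosphate, SCLAV_SC2_09415 (chromosome, 2313855–2315672), an enzyme type that feeds cell-wall precursors. It went from 47.2 ± 5.88 to 15049 ± 4342 CPM (SD, n = 3), 8.32 ± 0.41 log2 (SE, adjusted p = 2.01e-10). Neighbours near the right end of the chromosome rose together: the response regulator SCLAV_SC2_26260 (4.99), the hydrolase SCLAV_SC2_26265 (7.98, and at least 196-fold without SC2 replicate 3), the secreted protein SCLAV_SC2_26270 (6.46) and the membrane protein SCLAV_SC2_26275 (6.07). A methylmalonyl-CoA mutase gene, meaA, rose from 1.83 ± 0.815 to 126 ± 26.9 CPM (6.11). The hydrolase SCLAV_SC2_34155 of sequence 5 rose by 6.12, which is uncertain because a near-identical copy overlaps it on the other strand. Among the falls were the esterase SCLAV_SC2_30870 (-5.33) and the methyltransferase SCLAV_SC2_31205 (-4.66) of sequence 5. The moenomycin-type gene moeE5, an antibiotic pathway gene of the same sequence, fell by 5.07. For SCLAV_SC2_30870, SCLAV_SC2_31205 and moeE5 most of the SC5 level came from replicate 2 (2.43, 8.76 and 3.41 CPM), whose profile lies between those of SC5 and SC2. On the chromosome the sugar-binding protein SCLAV_SC2_07345 (-5.10), the nearby dehydrogenase SCLAV_SC2_07330 (-4.79) and AmfT homologue SCLAV_SC2_24200 (-4.42), from a family tied to aerial growth, fell. Of the tested genes of sequence 5, 300 of 536 fell and 35 rose (median -1.06). The fit without SC5 replicate 2 gave -5.997 for SCLAV_SC2_07330, -5.80 for SCLAV_SC2_07345, -5.04 for SCLAV_SC2_24200, -7.53 for SCLAV_SC2_30870, -6.02 for SCLAV_SC2_31205 and -7.06 for moeE5. Without SC5 replicate 3 the changes were -4.20 for SCLAV_SC2_07330, -4.52 for SCLAV_SC2_30870 and -3.83 for SCLAV_SC2_31205. Leaving SC5 replicate 1 out gave -4.23 for SCLAV_SC2_07345, -4.67 for SCLAV_SC2_30870 and -4.16 for moeE5. The fit without SC2 replicate 1 gave 6.85 for SCLAV_SC2_26275.

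Among sensing and repair genes more rose than fell in SC5. For two-component systems, which sense the surroundings, 61 of 123 tested genes rose and 15 fell (61 higher and 15 lower adjusted over the list alone), median 0.55 (camera adjusted p = 0.00136, alternatives 0.00114 to 0.598). A block of neighbours held the sensor kinase SCLAV_SC2_15455 (3.14), its regulator SCLAV_SC2_15460 (4.04) and the serine protease SCLAV_SC2_15465, which went from 20.0 ± 2.37 to 661 ± 289.6 CPM (5.05 ± 0.27 log2, SE, adjusted p = 4.54e-10); the histidine kinase SCLAV_SC2_14345 rose by 4.94. For DNA repair, 19 of 32 tested genes rose and 1, lexA_3, fell (20 higher and 1 lower adjusted over the list alone), median 0.55 (camera adjusted p = 0.00136, alternatives 0.000865 to 0.598), led by the excision gene SCLAV_SC2_05625 (1.54) and recO (1.57). For tRNA charging, 14 of 27 tested genes rose and 2, leuS and SCLAV_SC2_32280, fell (14 higher and 2 lower adjusted over the list alone), median 0.46 (camera adjusted p = 0.0464, alternatives 0.0231 to 0.722), with lysK at 1.41 and leuS at -0.995. For the respiratory chain, 16 of 38 tested genes fell and 1, nuoD, rose (1 higher and 16 lower adjusted over the list alone), median -0.45 (camera adjusted p = 0.0146, alternatives 0.00243 to 0.598); a chromosomal block of complex I genes was among the falls, with nuoB1 from 158 ± 31.0 to 25.8 ± 20.7 CPM (-2.73), nuoN1 (-3.10) and nuoC1 (-2.78). For secreted proteases and chitinases, 24 of 46 tested genes fell and 5, sprJ, SCLAV_SC2_08260, sprI, SCLAV_SC2_15465 and SCLAV_SC2_20030, rose (5 higher and 24 lower adjusted over the list alone), median -0.61 (camera adjusted p = 0.0464, alternatives 0.0189 to 0.598), among them the chitinase SCLAV_SC2_20875 (-3.06). In all, 3151 genes changed, 1610 higher and 1541 lower, 1952 by at least 1 log2 unit. Library-size scaling moved the median of all genes from 0.07 to 0.35 and the split to 2192 higher and 1166 lower, and scaling on chromosomal genes moved the median to -0.07. The protease list had an adjusted p of 0.0558 with a replicate block, and leaving out 1 library ended these calls (adjusted p in brackets): respiratory chain and ATP synthase without SC2 replicate 1 (0.0508), secreted proteases and chitinases without SC2 replicate 1 (0.0508), SC2 replicate 3 (0.0628) or SC5 replicate 3 (0.110), amino-acyl tRNA synthetases without SC2 replicate 2 (0.0711), SC2 replicate 3 (0.0828), SC5 replicate 1 (0.0571) or SC5 replicate 3 (0.0656), SCLAV_SC2_32280 without SC2 replicate 1 (0.0844) or SC5 replicate 2 (0.0860). Without SC5 replicate 2 the changes were -3.46 for nuoB1, -3.56 for nuoC1 and -4.08 for nuoN1.

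SC6 had no reads from the left end of sequence 5 in replicates 1 and 3. The stretch runs from the esterase SCLAV_SC2_30870 (start 11) to SCLAV_SC2_31145 (end 62755) and holds 56 genes, and it was singled out after its values were seen. In SC2 these genes together gave 7799 ± 1413 CPM (SD, n = 3), in SC3 7004 ± 634, in SC4 3944 ± 819.8 and in SC5 2339 ± 1035. Replicate 2 of SC6, 5126 reads of which fell in 45 of these genes, gave 2778 CPM. The profile of this library lies between those of SC6 and SC2, and mixed SC2 RNA or reads is a candidate explanation, taken up below. Fitted changes and calls with all libraries include it, so its reads bring the fitted levels of SC6 closer to SC2. The next gene, the carboxylesterase SCLAV_SC2_31150, had 83.3 ± 8.94 CPM in SC6 and 22.5 ± 3.43 in SC2. In the stretch, the MtrY homologue SCLAV_SC2_31030, a name shared with antibiotic-resistance loci, changed by -4.89 ± 0.80 log2 (SE, adjusted p = 0.00383). The cytochrome P450 SCLAV_SC2_30975, the resistance protein SCLAV_SC2_31045, the monooxygenase SCLAV_SC2_30970 and the esterase SCLAV_SC2_30870 had fitted changes of -4.66, -4.47, -4.31 and -4.90. Without the shallow libraries SC6 had 0 reads of these genes, so the levels were at least 50.7-fold lower for SCLAV_SC2_31030, 70.2-fold for SCLAV_SC2_30975, 84.7-fold for SCLAV_SC2_31045, 76.8-fold for SCLAV_SC2_30970 and 62.1-fold for SCLAV_SC2_30870. DESeq2 did not call SCLAV_SC2_30870, SCLAV_SC2_31045 and SCLAV_SC2_30970 with all libraries, and leaving out 1 library ended these calls (adjusted p in brackets): SCLAV_SC2_30975 without SC2 replicate 2 (0.0532), SC6 replicate 1 (0.0917) or SC6 replicate 3 (0.0965), SCLAV_SC2_31045 without SC6 replicate 1 (0.0743) or SC6 replicate 3 (0.0695), SCLAV_SC2_30970 without SC2 replicate 1 (0.0573), SC2 replicate 2 (0.0957), SC2 replicate 3 (0.0789), SC6 replicate 1 (0.165) or SC6 replicate 3 (0.165), SCLAV_SC2_30870 without SC2 replicate 2 (0.0602), SC2 replicate 3 (0.0651), SC6 replicate 1 (0.142) or SC6 replicate 3 (0.138). Leaving SC6 replicate 1 out gave -4.08 for SCLAV_SC2_30870, -3.44 for SCLAV_SC2_30970, -3.82 for SCLAV_SC2_30975, -4.10 for SCLAV_SC2_31030 and -3.60 for SCLAV_SC2_31045. The fit without SC6 replicate 3 gave -3.95 for SCLAV_SC2_30870, -3.31 for SCLAV_SC2_30970, -3.69 for SCLAV_SC2_30975, -3.96 for SCLAV_SC2_31030 and -3.48 for SCLAV_SC2_31045.

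**Figure D3:**
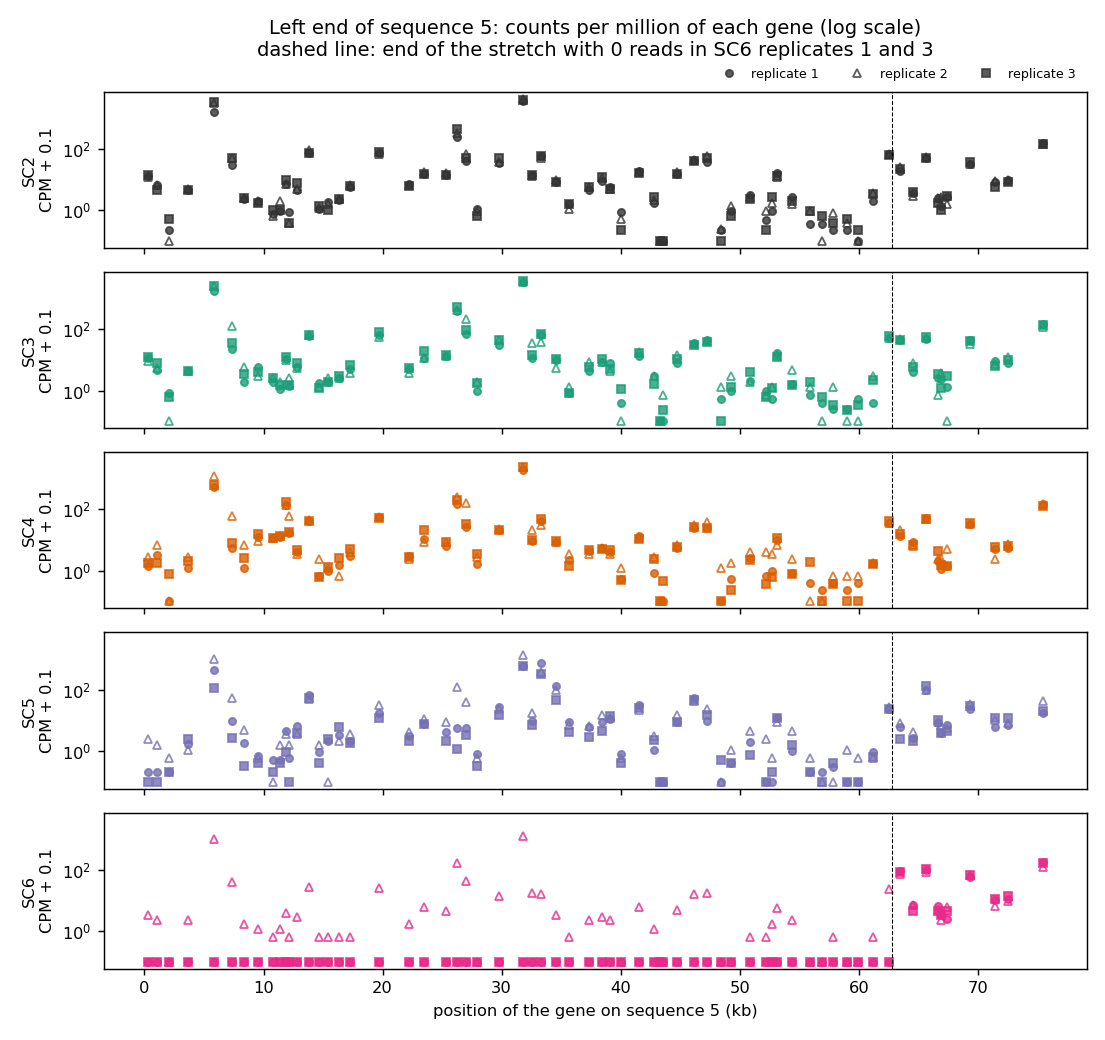
CPM plus 0.1 (log axis) of each gene by its position (kb) at the left end of sequence 5, in the libraries of the 5 strains; the dashed line marks the end of the stretch with 0 reads in replicates 1 and 3 of SC6. Replicate 2 of SC6 has reads in 45 of the 56 genes left of the line.

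On the chromosome of SC6, 3 neighbours rose together. Pyruvate phosphate dikinase SCLAV_SC2_26555 (6381560–6383386), which links pyruvate to gluconeogenesis, went from 51.3 ± 9.36 to 728 ± 134 CPM (SD, n = 3), 3.83 ± 0.22 log2 (SE, adjusted p = 1.47e-08), and the transcriptional regulators SCLAV_SC2_26560 and SCLAV_SC2_26565 beside it rose by 3.77 and 3.36. The efflux protein SCLAV_SC2_03140 rose by 2.14, to 639 ± 183 CPM. The regulator SCLAV_SC2_00620 rose by 2.22 and the transport protein SCLAV_SC2_11125 by 2.35 (adjusted p = 0.0258), while the oxidoreductase SCLAV_SC2_15730 fell from 12.2 ± 2.32 to 3.00 ± 1.64 CPM (-2.27). Of the 21 supercluster genes edgeR, DESeq2 and limma-voom called 0 in SC6, and 1 had an unadjusted p under 0.05 (median -0.06, camera adjusted p = 0.822, alternatives 0.735 to 0.954). Of 27 tested lists 1 passed (3 without SC2 replicate 1 and 4 without SC6 replicate 2), that of ribosomal proteins, with a median of 0.56 over 53 genes (camera adjusted p = 1.59e-15, alternatives 8.97e-18 to 0.596). Single ribosomal protein genes numbered 0 past the threshold in edgeR, 33 at an unadjusted p under 0.05, 30 adjusted over the list alone, and 6 in DESeq2 and 2 in limma-voom. In all, 180 genes changed, 102 higher and 78 lower, 124 by at least 1 log2 unit. The count was 400 without the 4 shallow libraries, 401 with a replicate block, and 111 without SC2 replicate 1, 57 without SC2 replicate 2, 73 without SC2 replicate 3, 47 without SC6 replicate 1 and 44 without SC6 replicate 3; scaling on chromosomal genes gave 77 higher and 98 lower. Leaving out 1 library ended the call of SCLAV_SC2_11125 without SC2 replicate 1 (0.0686), SC2 replicate 2 (0.128), SC2 replicate 3 (0.1004), SC6 replicate 1 (0.129) or SC6 replicate 3 (0.128), with the adjusted p in brackets.

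**Figure D4:**
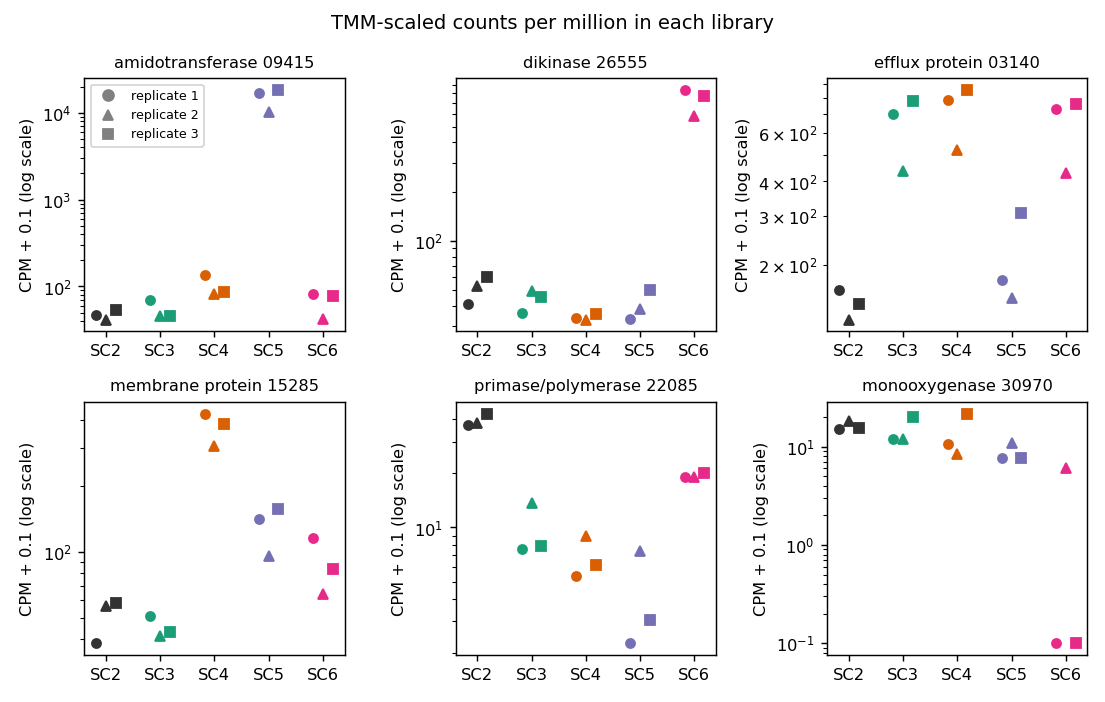
TMM-scaled CPM plus 0.1 (log axis) in each of the 15 libraries for 6 genes, named by product and by the last digits of the locus tag. The efflux gene SCLAV_SC2_03140 has 639 ± 183 CPM in SC6 and 145 ± 17.5 in SC2, and the amidotransferase gene SCLAV_SC2_09415 has 15049 ± 4342 in SC5.

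The comparisons of one strain number with the one before ask what differs from step to step, if the numbers give an order. Between SC3 and SC4 most arginine genes rose: 8 of 14 tested genes rose (12 higher and 0 lower adjusted over the list alone), median 1.00 (camera adjusted p = 5.13e-09, alternatives 5.13e-09 to 0.573). Ornithine carbamoyltransferase SCLAV_SC2_23535 went from 63.5 ± 18.7 to 178 ± 31.1 CPM (SD, n = 3), 1.48 ± 0.25 log2 (SE, adjusted p = 0.00233). For glycolysis, 1 of 24 tested genes rose (2 higher and 0 lower adjusted over the list alone), median 0.29 (camera adjusted p = 0.0130, alternatives 0.00919 to 0.769), the called gene being phosphoglycerate mutase gpmA1 (2.36). For ribosomal proteins, 0 of 53 tested genes rose (22 higher and 0 lower adjusted over the list alone), with 36 at an unadjusted p under 0.05, 11 called by DESeq2 and 3 by limma-voom, median 0.57 (camera adjusted p = 4.51e-14, alternatives 1.81e-16 to 0.769). For tRNA charging, 1 of 27 tested genes rose (1 higher and 0 lower adjusted over the list alone), median 0.29 (camera adjusted p = 0.000981, alternatives 8.71e-05 to 0.769), the called gene being aspS2 (0.74). The membrane protein SCLAV_SC2_15285 (3.05), the radical SAM protein SCLAV_SC2_24740 (4.06) and the MauE-domain protein SCLAV_SC2_30915 (3.31) rose. The ATPase-domain protein SCLAV_SC2_29335 fell from 27.6 ± 5.92 to 2.31 ± 0.895 CPM (-3.77), and so did the neighbouring chromosomal regulators SCLAV_SC2_00620 (-2.44) and SCLAV_SC2_00625 (-2.90). The clavam gene cvm1 changed by 1.81 and oat2 by 0.97. The supercluster had a median of -0.29 (camera adjusted p = 0.0769, alternatives 0.0722 to 0.876, 0.0198 without SC3 replicate 1 and 0.0237 without SC4 replicate 3). In all, 232 genes changed, 83 higher and 149 lower, 147 by at least 1 log2 unit. With a replicate block 459 changed, library-size scaling gave 90 higher and 107 lower, and the count was 148 without SC3 replicate 1, 74 without SC3 replicate 3, 72 without SC4 replicate 1 and 95 without SC4 replicate 3. Leaving out 1 library ended these calls (adjusted p in brackets): glycolysis and gluconeogenesis without SC3 replicate 2 (0.169) or SC4 replicate 3 (0.0644), amino-acyl tRNA synthetases without SC3 replicate 2 (0.112), aspS2 without SC3 replicate 1 (0.0517), SC3 replicate 3 (0.155), SC4 replicate 1 (0.0771) or SC4 replicate 3 (0.108), cvm1 without SC3 replicate 1 (0.0517), SC3 replicate 2 (0.0950), SC3 replicate 3 (0.106), SC4 replicate 1 (0.113) or SC4 replicate 3 (0.0995), oat2 without SC3 replicate 1 (0.0702), SC3 replicate 2 (0.147), SC3 replicate 3 (0.120), SC4 replicate 1 (0.154) or SC4 replicate 3 (0.165). Without the 4 shallow libraries the changes were -3.57 for SCLAV_SC2_00625.

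From SC4 to SC5 most arginine, ribosomal protein and beta-lactam genes were lower. In the supercluster 18 of 21 genes fell, median -1.43 (camera adjusted p = 1.66e-07, alternatives 5.90e-08 to 0.438). Without the 4 shallow libraries its median was -1.95. The clavam genes cvm1, from 752 ± 216 to 23.1 ± 17.1 CPM (SD, n = 3), -5.11 ± 0.48 log2 (SE, adjusted p = 1.70e-06), cvm3 (-5.35) and cas1 (-5.31), a clavaminate synthase, fell. For clavulanic acid and clavams 18 of 26 tested genes fell and 4, cvm11, ceaS1, bls1 and pah1, rose (4 higher and 19 lower adjusted over the list alone), median -1.49 (camera adjusted p = 5.18e-05, alternatives 1.11e-05 to 0.540), and for cephamycin C 13 of 14 tested genes fell (0 higher and 13 lower adjusted over the list alone), median -1.40 (camera adjusted p = 7.45e-05, alternatives 2.59e-05 to 0.572), as with lat (-1.69). For arginine 12 of 14 tested genes fell (0 higher and 13 lower adjusted over the list alone), median -1.58 (camera adjusted p = 7.34e-05, alternatives 2.59e-05 to 0.519), with oat2 at -2.08 and arginase SCLAV_SC2_00910 at -4.51. For ribosomal proteins 39 of 53 tested genes fell and 1, SCLAV_SC2_10150, rose (1 higher and 43 lower adjusted over the list alone), median -0.75 (camera adjusted p = 2.38e-06, alternatives 5.15e-08 to 0.758), led by rpsT (-1.10). For the respiratory chain 21 of 38 tested genes fell and 1, nuoD, rose (1 higher and 23 lower adjusted over the list alone), median -0.88 (camera adjusted p = 8.26e-05, alternatives 1.97e-05 to 0.519), with the cytochrome gene qcrC at -1.11 and the ATP synthase gene atpA1 at -0.93. For secreted proteases and chitinases 23 of 46 tested genes fell and 6 rose (7 higher and 24 lower adjusted over the list alone), median -0.90 (camera adjusted p = 0.0117, alternatives 0.00558 to 0.519); the serine protease SCLAV_SC2_15465 rose by 5.79 and the metalloprotease SCLAV_SC2_21215 fell by 4.13. The SC5 reads of cas1 lay mostly in replicate 2 (90.5 CPM against 16.3 and 1.89). With 1 library left out these calls ended (adjusted p in brackets): cvm11 without SC4 replicate 1 (0.0704), ceaS1 without SC4 replicate 3 (0.0533) or SC5 replicate 1 (0.0612), SCLAV_SC2_10150 without SC5 replicate 3 (0.0645), nuoD without SC4 replicate 1 (0.0580), SC4 replicate 2 (0.0566) or SC5 replicate 3 (0.0901). Leaving SC5 replicate 2 out gave -5.41 for SCLAV_SC2_00910, -7.11 for cas1, -5.70 for cvm1 and -6.44 for cvm3. The fit without SC5 replicate 3 gave -4.68 for cas1.

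For two-component systems, 54 of 123 tested genes rose and 14 fell (55 higher and 16 lower adjusted over the list alone) between SC4 and SC5, median 0.54 (camera adjusted p = 8.26e-05, alternatives 7.50e-05 to 0.519), again with SCLAV_SC2_15460 (4.37) and SCLAV_SC2_14345 (5.06). For DNA repair, 14 of 32 tested genes rose and 1, SCLAV_SC2_02650, fell (15 higher and 1 lower adjusted over the list alone), median 0.40 (camera adjusted p = 0.0151, alternatives 0.00558 to 0.540), with recO at 1.47. The amidotransferase SCLAV_SC2_09415 rose from 101 ± 29.3 to 15049 ± 4342 CPM (7.21) and the secreted protein SCLAV_SC2_26270 by 6.90. The hydrolase SCLAV_SC2_26265 had 0 reads in SC4 and was at least 214-fold higher in SC5. The methyltransferase SCLAV_SC2_31205 of sequence 5 fell from 93.4 ± 11.6 to 3.35 ± 4.73 CPM (-5.72). The sequence 5 synthase gene ceaS1 changed by 4.33 (adjusted p = 0.0112). In all, 2680 genes changed, 1278 higher and 1402 lower, 1600 by at least 1 log2 unit. Library-size scaling moved the median of all genes from 0.01 to 0.22 and the split to 1711 higher and 1072 lower, and a replicate block gave 3034 calls. Leaving out 1 library ended the call of ceaS1 without SC4 replicate 3 (0.0533) or SC5 replicate 1 (0.0612), with the adjusted p in brackets. Without SC5 replicate 2 the changes were -7.02 for SCLAV_SC2_31205. Leaving SC5 replicate 3 out gave -4.84 for SCLAV_SC2_31205 and 4.96 for ceaS1. The fit without SC5 replicate 1 gave 2.88 for ceaS1.

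Most beta-lactam genes stood higher in SC6 than in SC5. This comparison uses the same 3 SC5 libraries as those of SC5 with SC2 and with SC4, so the mirrored results are not independent. In the supercluster 21 of 21 genes rose, median 1.63 (camera adjusted p = 9.90e-09, alternatives 8.38e-10 to 0.438). Without the 4 shallow libraries its median was 1.996. The activator ccaR went from 781 ± 401 to 2679.7 ± 49.2 CPM (SD, n = 3), 1.78 ± 0.29 log2 (SE, adjusted p = 0.000118), and the peptide-binding gene oppA2 of the clavulanic acid cluster rose by 1.92. For clavulanic acid and clavams 20 of 26 tested genes rose and 4, cvm11, ceaS1, bls1 and pah1, fell (20 higher and 4 lower adjusted over the list alone), median 1.61 (camera adjusted p = 0.000196, alternatives 1.47e-05 to 0.682), and for cephamycin C 14 of 14 tested genes rose (14 higher and 0 lower adjusted over the list alone), median 1.77 (camera adjusted p = 1.11e-05, alternatives 1.02e-06 to 0.682). For arginine 6 of 14 tested genes rose (7 higher and 0 lower adjusted over the list alone), median 0.70 (camera adjusted p = 0.0352, alternatives 0.0209 to 0.764), with arginase SCLAV_SC2_00910 at 3.59 and oat2 at 1.42. For the respiratory chain 16 of 38 tested genes rose and 1, nuoD, fell (16 higher and 1 lower adjusted over the list alone), median 0.64 (camera adjusted p = 0.00383, alternatives 0.000368 to 0.682), with atpA1 at 0.82. For ribosomal proteins 14 of 53 tested genes rose (7 higher and 0 lower adjusted over the list alone), median 0.43 (camera adjusted p = 0.00471, alternatives 0.00115 to 0.835), with rpsT at 0.99. For two-component systems 50 of 123 tested genes fell and 15 rose (15 higher and 51 lower adjusted over the list alone), median -0.42 (camera adjusted p = 0.00196, alternatives 0.00138 to 0.682), and for DNA repair 16 of 32 tested genes fell and 1, SCLAV_SC2_02650, rose (1 higher and 17 lower adjusted over the list alone), median -0.51 (camera adjusted p = 0.00383, alternatives 0.00161 to 0.682), with the excision gene SCLAV_SC2_05625 at -1.59 and recA, the strand-exchange protein, at -1.52. The list of ribosomal proteins had an adjusted p of 0.0597 with library-size scaling, and leaving out 1 library ended the call of arginine and ornithine metabolism without SC5 replicate 3 (0.247), SC6 replicate 1 (0.147) or SC6 replicate 3 (0.107), cvm11 without SC6 replicate 1 (0.0888), ceaS1 without SC5 replicate 1 (0.113), SC6 replicate 1 (0.0758) or SC6 replicate 3 (0.0747), SCLAV_SC2_02650 without SC5 replicate 1 (0.102), SC5 replicate 2 (0.105), SC5 replicate 3 (0.0698), SC6 replicate 1 (0.194) or SC6 replicate 2 (0.0679), with the adjusted p in brackets. Without SC5 replicate 2 the changes were 4.50 for SCLAV_SC2_00910.

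Among single genes, the amidotransferase SCLAV_SC2_09415 was lower in SC6 than in SC5, at 67.1 ± 21.6 against 15049 ± 4342 CPM (-7.80 ± 0.40 log2, SE, adjusted p = 4.62e-10). The membrane protein SCLAV_SC2_26275 had 0 reads in SC6 and was at least 54.6-fold lower. The efflux gene arsB, of the arsenite pump type and inside the left end of sequence 5, had a fitted change of -7.74, and without the shallow libraries it was at least 417-fold lower. The ABC transporter gene SCLAV_SC2_16380 rose by 5.85, the methyltransferase SCLAV_SC2_31205 by 5.02 and the carbonic anhydrase SCLAV_SC2_00455 by 5.01. Of the tested genes of sequence 5, 250 of 536 rose and 57 fell (median 0.78). In all, 2748 genes changed between SC5 and SC6, 1437 higher and 1311 lower, 1675 by at least 1 log2 unit. Library-size scaling moved the median of all genes from -0.01 to -0.34 and the split to 984 higher and 2006 lower, and a replicate block gave 3130 calls. Leaving SC5 replicate 1 out gave 4.20 for SCLAV_SC2_00455. The fit without SC5 replicate 2 gave 6.89 for SCLAV_SC2_00455, 7.15 for SCLAV_SC2_16380 and 6.32 for SCLAV_SC2_31205. Without SC5 replicate 3 the changes were 4.31 for SCLAV_SC2_00455, 5.02 for SCLAV_SC2_16380 and 4.15 for SCLAV_SC2_31205. Leaving SC6 replicate 1 out gave -6.94 for arsB. The fit without SC6 replicate 3 gave -6.78 for arsB.

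**Figure D5:**
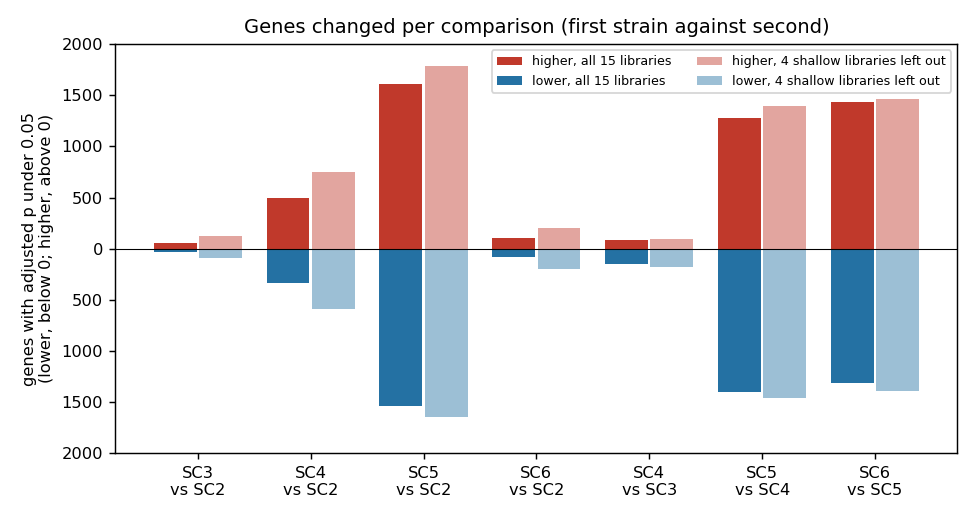
Genes with an adjusted p under 0.05 in each of the 7 comparisons, higher above 0 and lower below 0, with all 15 libraries and with the 4 shallow libraries left out. The bars of SC5 against SC2 hold 1610 higher and 1541 lower genes with all libraries.

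Stretches of 3 or more neighbouring genes with reads in SC2 and under 3 reads in each library of another strain were sought on all sequences. SC5 had 1, on sequence 5 from moeF5 (SCLAV_SC2_33510) to moeH5 (SCLAV_SC2_33520), genes annotated for making the cell-wall antibiotic moenomycin (642081–647299). Without SC5 replicate 2 it began at moeE5 and held 4 genes, and moeF5 was then at least 23.4-fold and moeH5 at least 18.9-fold lower than in SC2. SC3, SC4 and SC6 had 0. Without SC6 replicate 2 there were 5 in SC6 with 26 genes, all on sequence 5 between 2898 and 47929, from SCLAV_SC2_30885 to SCLAV_SC2_31075, and without SC2 replicate 3 there was 1. The other direction covers only genes of the SC2 annotation, to which all reads were assigned, so it cannot find genes that SC2 lacks. There, genes read in SC5 and silent in SC2 formed 0 such stretches with all libraries. Without SC5 replicate 2 they formed 1, on the chromosome from SCLAV_SC2_01815 to SCLAV_SC2_01825 (493265–495933). Without SC2 replicate 3 there was 1 too, on sequence 4 from SCLAV_SC2_30600 to SCLAV_SC2_30610 (395177–396191).

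Genes changed in the same direction in all 4 strains against SC2 numbered 14. Higher in all were the ABC transporter permease SCLAV_SC2_03830 and SCLAV_SC2_26875. The 12 lower ones included the replicative helicase SCLAV_SC2_27920, the GntR-family regulator SCLAV_SC2_27935 and SCLAV_SC2_27930, all of sequence 2. The levels of SCLAV_SC2_27935 and SCLAV_SC2_27930 are uncertain, as each has a near-identical copy on sequence 5. They also included the primase/polymerase SCLAV_SC2_22085, the RNA helicase SCLAV_SC2_19615, the regulator wblE_2, the terpene cyclase SCLAV_SC2_32015 and the cytochrome P450 SCLAV_SC2_33195. Independent lists of these sizes would share 0.0224 higher and 0.00710 lower genes. In 20 simulations all libraries, those of SC2 included, were drawn from the mean SC2 profile, and 0 genes were shared. The simulations held no changed genes, so they cannot show how many calls the real SC2 libraries make common to strains that change. By pair, the genes called in both comparisons numbered, with those of independent lists in brackets, 15 higher (4.78), 25 lower (2.07) and 3 opposite for SC3 and SC4; 10 higher (15.5), 35 lower (9.38) and 18 opposite for SC3 and SC5; 33 higher (0.983), 15 lower (0.475) and 1 opposite for SC3 and SC6. The numbers were 219 higher (135), 234 lower (88.5) and 80 opposite for SC4 and SC5; 36 higher (8.55), 32 lower (4.48) and 7 opposite for SC4 and SC6; 39 higher (27.8), 56 lower (20.3) and 32 opposite for SC5 and SC6. The efflux gene SCLAV_SC2_03140 is among those of SC3 and SC6. It is not particular to them, with 783, 520 and 854 CPM in SC4 against 162, 127 and 145 in SC2. In the simulations 0 genes were called in the same direction in any pair, but they held no changed genes to call. That 0 is therefore no yardstick for the pairs. The covariance of fold changes was above its simulated mean in each pair: 0.156 against 0.0661 for SC3 and SC4 (difference 0.0898), 0.182 against 0.0669 for SC3 and SC5 (difference 0.115), 0.156 against 0.0671 for SC3 and SC6 (difference 0.0889), 0.293 against 0.0653 for SC4 and SC5 (difference 0.227), 0.1798 against 0.0663 for SC4 and SC6 (difference 0.114), 0.246 against 0.0668 for SC5 and SC6 (difference 0.179). The correlation r was lower than simulated in pairs with SC5 and in SC4 and SC6 (r 0.278 against 0.474, 0.330 against 0.469, 0.292 against 0.477, 0.449 against 0.469 for SC3 and SC5, SC4 and SC5, SC5 and SC6, and SC4 and SC6), and r can fall where a strain's own changes grow. All 4 comparisons use the same 3 SC2 libraries, so part of an excess over independent lists or over the simulated covariance may come from them. The simulations drew each gene independently, without shifts that many genes of a library share. The count shared by all 4 was 1 without SC2 replicate 2, 0 without SC2 replicate 3, 52 with a replicate block and 58 without the 4 shallow libraries.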

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

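The settings that left out the 4 shallow libraries, the mismatched list members or genes with a near-identical copy, and DESeq2 size factors for the lists, were chosen after the data were seen, and the others before the data were examined. No setting reversed a call among the named genes or the lists. The supercluster, not called in SC3 and SC6 against SC2, had camera's direction up without SC2 replicate 2 or 3 in both and without SC3 replicate 1 in SC3, at medians of -0.08 to 0.05. In SC4 against SC2, 496 genes were higher and 340 lower, and 401 and 485 with scaling on chromosomal genes. With 3 libraries per strain, leaving out 1 leaves 2 for that strain, and counts fell or rose. The cause of the changes in counts below was not tested.

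Counts of changed genes moved with the setting. With the replicate block 190, 1347 and 401 genes changed in SC3, SC4 and SC6 against SC2, against 93, 836 and 180 without a block, and 459 against 232 between SC3 and SC4. With only the libraries of the strains compared the counts were 198, 1521 and 433 against SC2, and 503 for SC4 against SC3. Without the shallow libraries they were 213, 1339 and 400. For SC3 against SC2, limma-voom gave 146 and DESeq2 143. Asking for a change of at least 1 log2 unit as well left 305 and 1952 genes in SC4 and SC5 against SC2, 147 for SC4 against SC3, 1600 for SC5 against SC4 and 1675 for SC6 against SC5. Of 133 values for these 7 counts, 98 were within 1.5-fold. The 3286 genes that differ among 5 strains stayed within it in all 26 settings.

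Leaving out each library in turn gave 14 to 97 genes for SC3 against SC2, 182 to 962 genes for SC4 against SC2, 2673 to 3320 genes for SC5 against SC2, 44 to 205 genes for SC6 against SC2, 72 to 237 genes for SC4 against SC3, 2208 to 2962 genes for SC5 against SC4, 2238 to 3027 genes for SC6 against SC5, and 2824 to 3528 among the 5 strains. Where this leaves a strain with 2 libraries, the fit pools the spread over all strains. Lists that passed numbered 1 to 3 for SC3 against SC2, 4 to 6 for SC4 against SC2, 5 to 7 for SC5 against SC2, 1 to 4 for SC6 against SC2, 2 to 5 for SC4 against SC3, 8 to 8 for SC5 against SC4, 6 to 7 for SC6 against SC5. The adjusted p of the supercluster ran from 0.0367 to 0.822 for SC3 against SC2, 0.00365 to 0.184 for SC4 against SC2, 2.87e-09 to 7.10e-08 for SC5 against SC2, 0.0914 to 0.901 for SC6 against SC2, 0.0198 to 0.318 for SC4 against SC3, 6.20e-09 to 8.00e-07 for SC5 against SC4, 5.58e-10 to 1.87e-08 for SC6 against SC5. Runs of silent genes numbered 1 to 1 for genes silent in SC5 and read in SC2, 0 to 1 for genes silent in SC2 and read in SC5, and 0 to 5 for genes silent in SC6 and read in SC2. For the genes shared by all comparisons with SC2, only the 3 SC2 libraries were left out in turn, which gave 0 to 12.

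Among the gene lists, in the order SC3, SC4, SC5 and SC6 against SC2, SC4 against SC3, SC5 against SC4 and SC6 against SC5, 1, 5, 7, 1, 4, 8 and 7 passed with the preset correlation. With camera and an estimated correlation 0, 0, 0, 0, 0, 0 and 0 passed, and 0, 0, 0, 0, 0, 0 and 0 without the shallow libraries as well. By construction an estimated correlation widens the test where list members vary together. With fry, which asks whether a list moves one way without setting it against other genes, 0, 3, 16, 3, 1, 14 and 13 passed. Without the shallow libraries 2 passed for SC6 against SC2. With the estimated correlation the supercluster had an adjusted p of 0.438 for SC5 against SC2, 0.438 for SC5 against SC4 and 0.438 for SC6 against SC5. Of 2646 values for single lists, 2512 kept the primary outcome, called or not called, 91 lost a call and 43 gained one. Most lists were not called to begin with, and only lists that had passed could lose a call.

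The share of reads of sequence 3 differed among strains with TPM (adjusted p = 0.0251, exact permutation test) and not with counts. Of 170 values for mean shares, 127 lay within 1 SD. With a limit of 10 reads, SC4 had 1 silent run, SC5 6 and SC6 3, and genes silent in SC2 and read in SC5 formed 1. With 2 or more genes there was 1 of these and 1 in SC6. SC5 had 0 with 5 or more genes, and 0 with TPM below 1 as the limit. Without the shallow libraries SC6 had 5 and the genes silent in SC2 and read in SC5 formed 1. The overlap of all 4 comparisons with SC2 was 35 genes with DESeq2, 6 with a change of at least 1 log2 unit, 52 with the replicate block and 58 without the shallow libraries. For 436 pairs of a named gene and a comparison, 7446 of 7796 values kept the primary outcome, called or not called. A call was lost in 249 and gained in 101.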

Other observations

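Several lists that camera did not call held single genes that changed in SC5 against SC2 by edgeR's test. In nitrogen assimilation, 6 of 14 tested genes were called higher and 1 lower (6 and 1 adjusted over the list alone), with a median of 0.67 (camera adjusted p = 0.0967). The glutamate synthase subunit gltD rose by 3.96, its partner SCLAV_SC2_05965 by 3.75, and the glutamine synthetase genes glnA3 and glnA2 by 4.24 and 2.65. Without SC5 replicate 3 these were 3.35 for gltD, 3.15 for SCLAV_SC2_05965 and 3.59 for glnA3. In glycolysis and gluconeogenesis, 12 of 24 tested genes were called higher and 3 lower (12 and 4 adjusted over the list alone), with a median of 0.62 (camera adjusted p = 0.0568), and the list passed without SC5 replicate 1 (0.0390). Its risers included the dikinase SCLAV_SC2_08120 (2.81), phosphoenolpyruvate carboxykinase SCLAV_SC2_18855 (2.61) and the fructose bisphosphatase glpX (2.03). In the phosphate starvation response, 4 of 12 tested genes were called higher and 0 lower (4 and 0 adjusted over the list alone), with a median of 0.48 (camera adjusted p = 0.151). There phoH rose by 1.46, the sensor phoR by 1.41 and the permease pstA by 1.78. Of 10 members of the list for glycerol uptake and use, edgeR called 3. In that list glpK and glpF1 fell by 3.07 and 3.49.

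Genes of development went both ways in SC5. In sporulation and aerial growth, 8 of 39 tested genes were called higher and 14 lower (8 and 14 adjusted over the list alone), with a median of -0.22 (camera adjusted p = 0.502). The WhiB-family regulator SCLAV_SC2_10260 rose by 3.90 and ssgD by 3.65, while the oligopeptide transport gene bldKE fell by 1.81 and the sporulation-control gene SCLAV_SC2_26940 by 2.58 (-3.20 without the 4 shallow libraries). Among sigma and anti-sigma factors, 15 of 54 tested genes were called higher and 11 lower (15 and 11 adjusted over the list alone), with a median of 0.10 (camera adjusted p = 0.521), and the extracytoplasmic sigma factors SCLAV_SC2_18575 and SCLAV_SC2_11505 rose by 3.75 and 3.59. In terpene biosynthesis, 5 of 28 tested genes were called higher and 11 lower (5 and 11 adjusted over the list alone), with a median of -0.45 (camera adjusted p = 0.304), and the pentalenene synthase SCLAV_SC2_34110 fell by 1.65. Among polyketide and peptide synthetases, 3 of 29 tested genes were called higher and 7 lower (3 and 7 adjusted over the list alone), with a median of -0.46 (camera adjusted p = 0.445), with SCLAV_SC2_26770 falling by 2.08. Among beta-lactamases and penicillin-binding proteins, 15 of 36 tested genes were called higher and 13 lower (16 and 13 adjusted over the list alone), with a median of 0.24 (camera adjusted p = 0.829), and SCLAV_SC2_05300 and SCLAV_SC2_19200 rose by 4.35 and 4.34.

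The tests of SC2 RNA mixed into replicate 2, of depth at the genes silent in SC6, in SC3, SC4 and SC6 and in SC5 taken apart, of scaling and of SC5 without replicate 2 were chosen after the result was seen. In the 4 shallow libraries the profile lay between that of the strain and that of SC2. Fitted with replicates 1 and 3 as sources, the SC2 share was 0.471 in SC3, 0.403 in SC4, 0.291 in SC5 and 0.462 in SC6 replicate 2. With replicate 3 alone as source it was 0.278, 0.233, 0.1002 and 0.364. That fit is rough for single libraries. With the same source, replicate 1 of SC2 was fitted as 0.431 SC2, with 0.301 as the highest share of another strain. Replicate 1 of SC3 to SC6 was fitted as 0.534, 0.969, 0.736 and 0.973 its own strain. Lower depth alone is argued against at 37 genes with under 3 reads in each of replicates 1 and 3 of SC6 and at least 10 in each SC2 library: replicate 2, the shallowest, held 5114 reads of them and replicates 1 and 3 together 2. In SC3 to SC6, replicate 1 was thinned to the same depth, with replicate 3 as source. Its SC2 share was 0 in each of 50 draws per strain. The lowest gap among SC3, SC4 and SC6 was 0.233 against a limit of 0.1, which argues against depth alone there. In SC5 the gap of 0.1002 exceeds the limit by less than its resampling SD of 0.00345. There, 327 genes lay 2 log2 units or more from SC2 in replicates 1 and 3, and replicate 2 was on the SC2 side of both at a share of 0.817. Reads drawn at its depth gave at most 0.183 in 50 draws, and replicates 1 and 3 in its place 0.175 and 0.397, which argues against depth alone in SC5 as well. Mixed SC2 RNA or reads is a candidate explanation: the median ratio of SC6 replicate 2 to SC2 at those genes was 0.360 (quartiles 0.292 to 0.466), near the fitted share of 0.462. Living SC2 cells in that culture and RNA mixed in later cannot be told apart, since both give the same counts, and no biological explanation was tested.

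SC5 differed from SC2 at 3151 genes. Scaling as the whole cause of the count is argued against, since under 3 other scalings the lowest count was 3109. This does not cover which genes changed or their direction. With library size 3358 genes were called, 2192 higher and 1166 lower, and 2776 of them were among the primary calls. Replicate 2 of SC5 does not make the calls alone, since 3320 genes were called without it. A later or earlier growth stage of the SC5 cultures could give such a shift and cannot be told apart from the strain, because each strain was sampled at 1 stage. The ribosomal protein genes, which often follow growth, had a median of 0.20, and ribosomal RNA took 3.46% of reads in SC5 against 1.95% in SC2. The genotype of SC5 stays open as the biological explanation, untested here.

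The 9 tested genes of sequence 2 lay lower than in SC2 in all 4 strains, with medians of -1.45, -1.38, -2.16 and -1.35 in SC3 to SC6; 3, 6, 8 and 3 of them were called by edgeR. A single SC2 library that stands apart is argued against, as the highest of 12 medians with 1 SC2 library left out was -1.25. Shared reads explain at most part: 4 genes have a near-identical copy elsewhere, and the other 5 had medians of -1.08, -0.70, -1.31 and -1.13, with 1, 2, 4 and 1 called. Fewer copies of the element per cell may lower its genes together, and this cannot be told apart from lower transcription in RNA. The lowest SD over its genes was 0.558 log2 units, and all 4 comparisons share the SC2 libraries.

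Other splits of the libraries were tried for each count of changed genes. The 6 libraries of a comparison make 10 splits, too few for a share under 0.05. In each of the 7 comparisons 1 split, the real one, gave as many calls. The highest of the other splits was 1 for SC3 against SC2 (real 93) and 1 for SC5 against SC2 (real 3151). It was 0 for SC4 and SC6 against SC2 (real 836 and 180), SC4 against SC3 (232), SC5 against SC4 (2680) and SC6 against SC5 (2748). Where replicate numbers pair the libraries, the other splits that part all 3 pairs gave 0 calls, and the call for SC3 came from a split that parts 1 pair. Among the 5 strains, 1 of 100 splits, the real one, gave as many as 3286 genes, the smallest share that 100 splits can give. The highest others gave 2075 and 1819. This argues against chance as the source of the full count, but wrong groupings can also give large counts.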
